A study of Homo sapiens with 12 samples.

How the data were processed

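Gene expression was measured on Affymetrix Human Gene ST arrays, single-colour arrays with biotin label, in 231BR cells sorted by EGFP. There were 12 arrays in 4 groups of 3, and the labels give the treatment and culture of each. The deposited values are on the log2 scale, and the submitters' processing notes name RMA and Partek without versions and without the role or order of each. RMA background-corrects, quantile-normalizes and summarises probes into probe sets. The deposited columns have medians from 4.35 to 4.77 per array, and the SD of the columns differs between arrays. Arrays have no read depth, so the number of arrays limits the precision.

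The probe table names genes for 21236 of the probe sets in the files, 19181 with 1 gene symbol and 2055 with several, and 12061 are not in it. Probe sets with 1 symbol were used. For the 895 genes with several such probe sets, the probe set with the highest mean over the 12 arrays was taken, which left 17958 genes. No filter on low values was applied. The RefSeq annotation of GRCh38.p14 was used for older symbols and for gene length, known for 17930 genes (99.8%).

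Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit on 1 mean per group over all 12 arrays, contrasts.fit and eBayes without trend or robust options. All tests were two-sided. The p-values of each contrast were adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. The 5 contrasts were estradiol against vehicle without astrocytes, the same with astrocytes, astrocytes against none under vehicle, the same under estradiol, and the interaction. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1.

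Before the data were examined, 40 gene lists with 987 members in all (917 measured) were fixed, for signalling, invasion, inflammation, stress, metabolism, cell cycle and the cell types that an astrocyte culture may hold. They were tested with camera, which compares a list with all other genes, with a preset correlation of 0.01, and adjusted over the lists of each contrast. Beside it stood camera with an estimated correlation, camera with a correlation of 0.05, and fry, which tests whether a list's genes move one way on balance. Members were also counted past the threshold when adjusted over the list alone. In sentences that give several lists, a bare value in parentheses after a list is camera's adjusted p.

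Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, leaving out microRNA genes, open reading frame names and the like, or the 10 genes with the smallest p where fewer than 5 pass. It also takes up to 4 members of each list described, those with the smallest p, and 6 fixed genes (S100A4, EGFR, ESR1, ESR2, GPER1 and PGR) in every contrast. The text names those of them that it describes, and any other gene is said to have been chosen after its values were seen.

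The alternatives planned before the data were examined were the replicate number as a block, quantile normalization of the deposited values, centring each array on its median, genes above the median level, every probe set on its own, the mean of a gene's probe sets, eBayes with trend and robust options, arrayWeights, no moderation of the variance, the arrays of the compared groups only, other thresholds, and each array left out in turn. Where a group had 2 arrays left, limma pooled the spread over all groups. Chosen after seeing the data were the SD of each array's values as a covariate, leaving out replicate 2 of both astrocyte groups, and the mean of both astrocyte comparisons (6 arrays against 6). The same holds for camera with both the array SD and an estimated correlation, and for the place of each list's median in each astrocyte comparison among 10000 random lists matched on level in vehicle alone. Between the 2 astrocyte groups the deviations of same-number arrays from their group means correlated over 0.1 in all 3 pairs (r = 0.789, 0.756 and 0.214). Replicate 3 of estradiol with astrocytes correlated more with replicate 1 of vehicle with astrocytes (r = 0.396), so the values do not favour its own number. These groups were therefore also compared as 3 pairs, a pairing taken from the values, since the labels do not say what a number marks.

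The pipeline was tested on simulated data of the same shape. A true log2 change of 1 was recovered for 18.7% of changed genes and a change of 2 for 74.0%, with 4.67 false calls on average, and a list shifted by −0.5 was recovered each time. The noise there was drawn independently for each gene. The recovery of that list therefore does not show how camera with its preset correlation behaves where the genes of a list move together. A further simulation changed only each array's range of signal, set by its measured SD, with the same independent noise for every gene. At most 1 gene per comparison was called on average. It lacks the gene-specific spread and the shared deviations of the real arrays, so it does not show that signal range cannot produce calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.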

Results

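RNA was measured in 231BR cells, a brain-seeking derivative of the human MDA-MB-231 breast cancer line, which lacks estrogen receptor alpha. The cells carried EGFP and received vehicle or 10 nM estradiol, either alone or in culture with mouse astrocytes. After 24 h of co-culture the EGFP-positive human cells were sorted from the astrocytes. The 12 arrays form 4 groups of 3, named here vehicle alone, estradiol alone, vehicle with astrocytes and estradiol with astrocytes. Probe sets with 1 gene symbol numbered 19181, and 17958 genes were compared. By its title, the series asks how estrogen acts on 231BR cells through astrocytes that have the estrogen receptor. The labels do not say whether replicates were separate cultures, so the p-values measure a spread between samples that may be technical, and the number of arrays limits the precision.

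The arrays with astrocytes had a narrower range of signal. The SD of the log2 values on an array averaged 2.14 ± 0.094 (SD, n = 3) in vehicle alone and 2.16 ± 0.042 (SD, n = 3) in estradiol alone. It averaged 1.94 ± 0.11 (SD, n = 3) in vehicle with astrocytes and 1.89 ± 0.24 (SD, n = 3) in estradiol with astrocytes. Replicate 2 of estradiol with astrocytes had the lowest SD, 1.62, and correlated with the 6 arrays without astrocytes at r from 0.638 to 0.739 across genes. Replicate 2 of vehicle with astrocytes followed, with an SD of 1.82 and r from 0.837 to 0.906. The 6 arrays without astrocytes correlated with each other at r of 0.961 or more. Component 1 held 79.9% of the variance and component 2 held 8.95%.

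**Figure D1:**
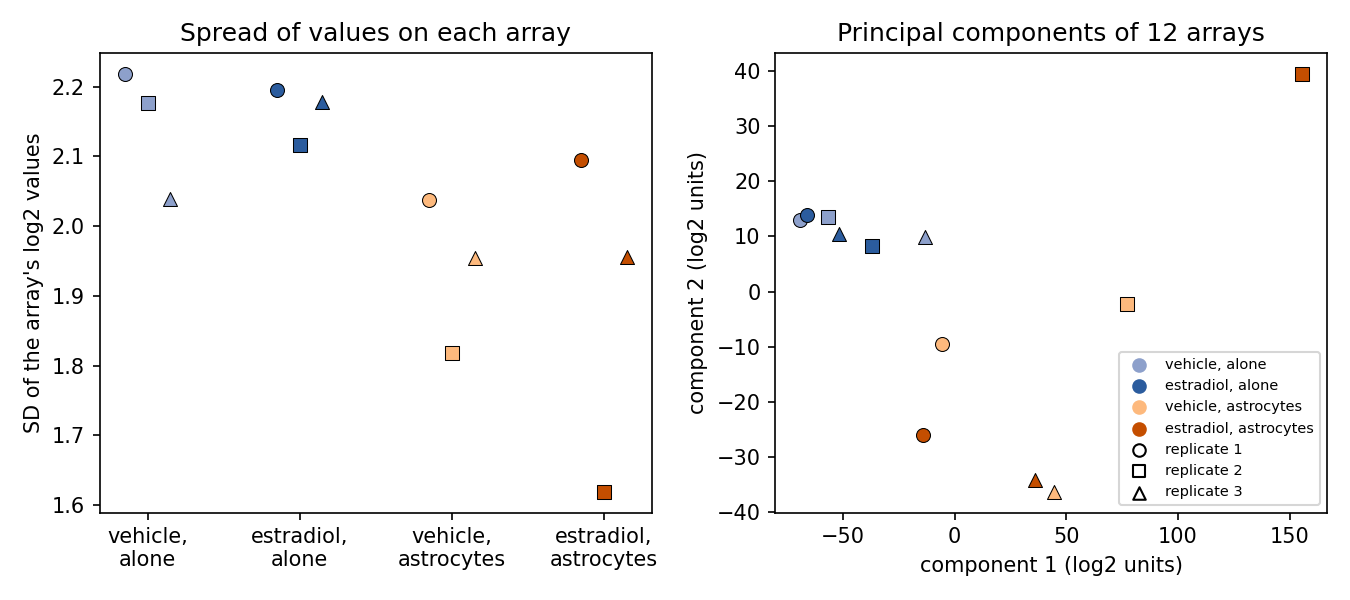
Left, the SD of the log2 values on each of the 12 arrays, by group (replicate 1 circle, replicate 2 square, replicate 3 triangle); right, the same arrays on principal components 1 and 2, in log2 units. Replicate 2 of estradiol with astrocytes, with an SD of 1.62, lies farthest from the arrays without astrocytes.

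The comparison of vehicle with astrocytes against vehicle alone asks what astrocytes do to the tumour cells without estradiol. PTGS2 (probe set 7922976), which encodes the prostaglandin-forming enzyme COX-2, fell 6.22-fold, from 7.69 ± 0.12 (SD, n = 3) to 5.05 ± 0.35 (SD, n = 3) on the log2 scale. IL6 (probe set 8131803), an inflammatory cytokine gene, fell 4.28-fold, from 6.31 ± 0.20 (SD, n = 3) to 4.21 ± 0.16 (SD, n = 3). H2AC15 (probe set 8124524), a histone H2A gene, rose 4.31-fold, from 7.34 ± 0.28 (SD, n = 3) to 9.45 ± 0.53 (SD, n = 3). TERC, the RNA component of telomerase, rose by 1.89 (SE 0.26) and TMA7 by 1.07 (SE 0.16). DNHD1 fell by 1.86 (SE 0.23) and MGC70870 by 1.65 (SE 0.22). The adjusted p in limma was 0.00203 for PTGS2, 0.00338 for IL6, 0.0263 for H2AC15, 0.0335 for TERC, 0.0470 for TMA7, 0.0241 for DNHD1 and 0.0307 for MGC70870, and for each of PTGS2, IL6 and H2AC15 no array of either group overlapped the other group. IL1B, at −2.78, and CSF3, at −1.22, did not pass, with adjusted p of 0.0657 and 0.0522.

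Of 17958 genes, 10 passed, 3 higher and 7 lower with astrocytes, and 5073 had an unadjusted p under 0.05. The other 3 of the lower genes were microRNA genes, MIR218-1 (−1.73), MIR30C2 (−2.27) and MIR30E (−1.28), named here only after their values were seen. Signals of the 3 arrays of each group did not overlap for 41.8% of genes, against 10% by chance. Leaving out any 1 array changed the count. It was 2 genes, PTGS2 and IL6, without estradiol alone replicate 2 or 3, without vehicle alone replicate 1, 2 or 3, and without vehicle with astrocytes replicate 2 or 3. It was 3 genes without estradiol alone replicate 1 (PTGS2, IL6 and DNHD1) and without estradiol with astrocytes replicate 3 (PTGS2, IL6 and MGC70870). It was 1122, 6107 and 1630 genes without estradiol with astrocytes replicate 1, estradiol with astrocytes replicate 2 and vehicle with astrocytes replicate 1, and these included the same 10 genes. The 6 arrays of these groups fitted on their own gave 1594 genes and the array SD as covariate gave 1166, each with the same 10 among them.

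Among the 40 gene lists fixed before the data were examined, NF-kB inflammatory genes were lower with astrocytes under vehicle. Of the 33 measured, 2 fell (PTGS2 and IL6) when adjusted over all genes, and 14 fell and 1 rose when adjusted over the list alone. The median was −0.37, and camera gave an adjusted p of 0.00448. All 39 measured replication-dependent histone genes, whose RNAs are made in S phase, had positive changes, with H2BC9 at 1.58 and H4C2 at 0.96. No single member passed over all genes and 1 did when adjusted over the list alone, the median was 0.52, and the list's adjusted p was 5.96e-06. With an estimated correlation neither list passed (adjusted p = 0.205 for NF-kB inflammatory genes and adjusted p = 0.674 for histones). Leaving out any 1 array kept both calls, with an adjusted p of at most 0.0319 for NF-kB inflammatory genes and 0.000780 for histones. Among random lists matched on level the histone median lay above the middle 95%, and that of NF-kB inflammatory genes, at percentile 4.34, lay inside it.

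A further 12 lists passed under vehicle, and none of them held with an estimated correlation (adjusted p = 0.674 or more). The unfolded protein response list, genes for folding and degrading proteins in the endoplasmic reticulum, had a median of −0.74 (adjusted p = 0.000489), with EDEM1 at −1.94, HSPA5 at −1.50 and HERPUD1 at −1.73. The medians were −0.51 for YAP target genes (adjusted p = 0.00123), −0.44 for the ATF4 and amino acid response (0.00218), −0.60 for the hypoxia response (0.00218) and −0.56 for ERK pathway output (0.0281). Fatty acid synthesis had a median of −0.81 (0.00640), the S phase list −0.54 (0.0130), the G2 and mitosis list −0.66 (0.00113) and the oxidative stress response −0.42 (0.0422). Epithelial markers had a median of 0.52 (0.00448), with CRB3 at 1.48 and KRT7 at 0.79. Over all genes no member of these 12 lists passed. Adjusted over the list alone, 9 members of the ATF4 list, 6 of the YAP list, 6 of the hypoxia list and 4 of the unfolded protein response list fell. Markers of microglia and macrophages (median 0.49, adjusted p = 0.00726, SPI1 at 1.29) and of neurons (median 0.40, 0.00972, STMN2 at 1.07) had positive medians too. Of these 12 lists only epithelial markers, at percentile 99.3, lay outside the middle 95% of random lists matched on level. The microglia and neuron markers, at percentiles 94.0 and 56.2, lay inside it.

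With the SD of each array as a covariate, which was added after seeing the data, the histone list (adjusted p = 8.90e-05), NF-kB inflammatory genes (8.90e-05) and epithelial markers (0.00781) kept their calls under vehicle. When the correlation was estimated in that fit too, none passed (adjusted p = 0.747, 0.0515 and 0.747). The S phase list turned upward (0.00686, and 0.747 with the correlation estimated in that fit), and the G2 and mitosis list turned upward without passing (0.0751). The unfolded protein response (0.0589), YAP (0.252), ATF4 (0.177), hypoxia (0.593), ERK (0.742), fatty acid synthesis (0.742), microglia (0.742), and neuron (0.742) lists no longer passed, and the oxidative stress list turned upward without passing (0.980). Without vehicle with astrocytes replicate 2 the S phase list did not pass (0.126). The ERK list did not pass without vehicle with astrocytes replicate 2 or 3, up to an adjusted p of 0.0645. The oxidative stress list did not pass without vehicle alone replicate 1 or vehicle with astrocytes replicate 1 or 2, up to 0.113.

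**Figure D2:**
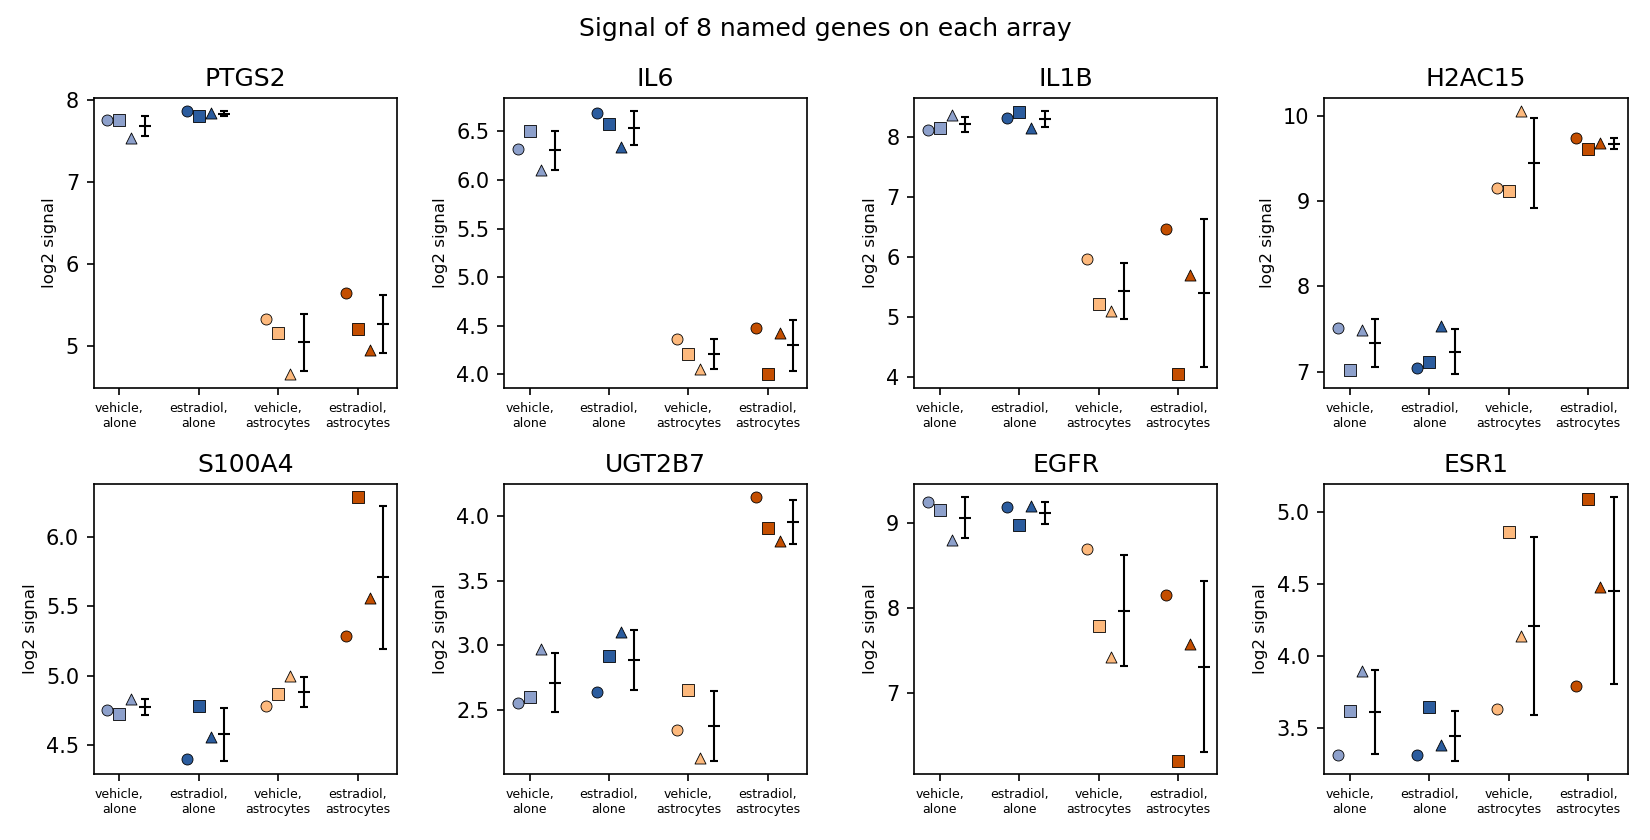
Log2 signal of 8 genes on each of the 12 arrays, by group (replicate 1 circle, replicate 2 square, replicate 3 triangle), with the group mean and SD as a bar with whiskers. PTGS2, IL6 and IL1B lie lower and H2AC15 higher on every array with astrocytes than on any array without.

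The comparison of estradiol with astrocytes against estradiol alone asks what astrocytes do in the presence of the hormone. PTGS2 fell by 2.56 on the log2 scale, from 7.84 ± 0.029 (SD, n = 3) to 5.27 ± 0.35 (SD, n = 3), and IL6 fell by 2.23, from 6.53 ± 0.18 (SD, n = 3) to 4.30 ± 0.26 (SD, n = 3). IL1B (probe set 8054722), another inflammatory cytokine gene, fell by 2.89 to 5.40 ± 1.23 (SD, n = 3), and CSF3, which encodes a granulocyte growth factor, fell by 1.30. H2AC15 rose by 2.44 to 9.68 ± 0.065 (SD, n = 3) and the histone H2B gene H2BC9 rose by 2.23. The adjusted p in limma was 0.00120 for PTGS2, 0.00120 for IL6, 0.0294 for IL1B, 0.0210 for CSF3, 0.00591 for H2AC15 and 0.0332 for H2BC9. Apart from histones, other large rises were those of CELP (2.47), DGCR11 (2.34), KRTAP10-12 (2.19), AOC3 (2.04), KRTAP10-2 (2.04), CSH2 (1.99) and IGSF9B (1.96). Other large falls were those of LRRFIP1 (−3.46, but −2.05 without estradiol with astrocytes replicate 2), NBPF20 (−3.22, but −2.14 without that array), ZNF737 (−3.02), SLC7A11, the cystine transporter gene (−3.01), BLID (−2.99), PBRM1 (−2.90), MALAT1 (−2.88) and TOR1AIP2 (−2.83). Without single arrays the smallest falls were −2.10 for ZNF737, −2.18 for SLC7A11, −2.80 for BLID, −2.01 for PBRM1, −1.96 for MALAT1 and −2.03 for TOR1AIP2. The smallest rises were 1.85 for CELP, 1.66 for DGCR11, 1.73 for KRTAP10-12, 1.45 for AOC3, 1.40 for KRTAP10-2, 1.53 for CSH2 and 1.57 for IGSF9B. For each of these genes the adjusted p in limma rose above 0.15 without at least 1 array.

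Of 17958 genes, 2366 passed, 903 higher and 1463 lower with astrocytes, and 7880 had an unadjusted p under 0.05. Signals did not overlap for 50.9% of genes, against 10% by chance. All 10 genes called under vehicle were called in the same direction here, although the 2 comparisons are not independent, since 1 fit over all 12 arrays gives each gene the same spread in both. Across genes the changes under vehicle and under estradiol correlated at r = 0.944 (rho = 0.937), but genes are not independent replicates and both comparisons follow the level of signal, as described below. The count was 3 genes (PTGS2, IL6 and MGC70870) without estradiol alone replicate 1, estradiol alone replicate 2 or estradiol with astrocytes replicate 3. It was 5 without estradiol alone replicate 3 (these 3, H2AC15 and MIR218-1), 13 without vehicle alone replicate 1 and 10 without vehicle alone replicate 2. It was 1547 without vehicle alone replicate 3, 1032 without vehicle with astrocytes replicate 3, 9222 without estradiol with astrocytes replicate 1 and 416 without estradiol with astrocytes replicate 2. The 6 arrays of these groups fitted on their own gave 0 genes in limma, so that fit turns round the order of the 2 counts, 10 under vehicle against 2366 here. With quantile normalization the count was 529, and with the array SD as covariate it was 469, of which 215 were among the 2366.

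Under estradiol, 12 of the 33 measured NF-kB inflammatory genes fell and none rose when adjusted over all genes, and 15 fell and 5 rose when adjusted over the list alone. The median was −0.50 and the list's adjusted p was 0.00938. Of the 39 measured histone genes, 9 rose over all genes and 18 when adjusted over the list alone, among them H3C11 (1.84) and H4C2 (1.09). The histone median was 0.66 and the list's adjusted p was 5.30e-07. Neither list passed with an estimated correlation (adjusted p = 0.357 for NF-kB inflammatory genes and adjusted p = 0.579 for histones). Both held with the array SD as covariate, with adjusted p of 7.28e-06 and 5.86e-08, and when the correlation was estimated in that fit too NF-kB inflammatory genes had an adjusted p of 0.0278 and histones of 0.548. Without estradiol with astrocytes replicate 1 the NF-kB list had an adjusted p of 0.0548. Its median lay at percentile 7.19 of random lists matched on level, inside their middle 95%, and that of histones lay above it.

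Stress and growth lists also had negative medians with astrocytes under estradiol, and none held with an estimated correlation (adjusted p = 0.579 or more). Of the 4 lists in this paragraph only the unfolded protein response, at percentile 0.40, lay below the middle 95% of random lists matched on level, while the YAP, ATF4 and ERK lists, at 20.04, 8.87 and 29.02, lay inside it. In the unfolded protein response list 7 of 22 members fell over all genes and 17 over the list alone, with SEL1L at −2.14, HSPA5 at −2.01 and EDEM1 at −1.91, and 1 and 2 members rose (median −1.23, adjusted p = 6.31e-05). Of 25 YAP target genes, 10 fell over all genes and 15 over the list alone, among them CRIM1 (−2.13), ASAP1 (−1.63) and AMOTL1 (−0.88), with a median of −0.85 (adjusted p = 3.88e-05). In the ATF4 list 9 of 35 fell over all genes and 11 over the list alone, among them CTH (−1.81) and VLDLR (−1.33), with a median of −0.82 (adjusted p = 0.000641). ERK pathway output had 7 of 24 members lower and 1 higher over all genes and 15 lower and 1 higher over the list alone. SPRED1 (−2.01) and CCND1 (−1.02) fell, SPRED3 rose (1.33), and the list's median was −0.85 (adjusted p = 0.000641). These 4 lists kept their calls with the array SD as covariate, with adjusted p of 0.00665, 0.00403, 0.0191 and 0.0257 in the order given, but not when the correlation was estimated in that fit (0.548 for each).

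In the hypoxia list 6 of 27 members fell over all genes and 7 over the list alone, among them LOX (−2.57), STC1 (−1.59) and VEGFA (−1.27), with a median of −0.81 (adjusted p = 0.00116). In fatty acid synthesis 4 of 17 fell over all genes and 9 over the list alone, among them ACACA (−1.68) and SCD (−0.94), with a median of −1.20 (adjusted p = 0.00108), and ACACA was at −1.12 without estradiol with astrocytes replicate 2. In the G2 and mitosis list 4 of 40 fell, among them MKI67 (−2.04), CENPE (−1.94) and CENPF (−1.86), with a median of −1.01 (adjusted p = 3.88e-05). In the S phase list 2 of 38 fell, HELLS (−2.14) among them, and 1 rose, with a median of −0.78 (adjusted p = 0.00187). None of these 4 lists passed with an estimated correlation (adjusted p = 0.579 or more), and all lay inside the middle 95% of random lists matched on level, at percentiles 18.9, 2.89, 10.8 and 61.9 in the order given. Adding the array SD as covariate, the hypoxia (adjusted p = 0.452) and fatty acid synthesis (0.450) lists no longer passed, the S phase list turned upward (0.00572, and 0.548 with the correlation estimated in that fit), and the G2 and mitosis list turned upward without passing (0.231). Without estradiol with astrocytes replicate 2 the S phase list had an adjusted p of 0.346.

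The lists for brain metastasis and for migration and invasion had negative medians with astrocytes under estradiol, although neither passed with an estimated correlation (adjusted p = 0.579 for both) and both lay inside the middle 95% of random lists matched on level, at percentiles 10.9 and 43.3. In the brain metastasis list 5 of 22 fell over all genes and 9 over the list alone, among them PTGS2, EREG (−2.26), an EGFR ligand gene, and LAMA4 (−1.68), while PLAAT4 rose (1.11). Its median was −0.41 (adjusted p = 0.0358), which became 0.0543 without estradiol with astrocytes replicate 3 and 0.144 with the array SD as covariate, and EREG was at −1.49 without estradiol with astrocytes replicate 2. In the migration and invasion list 6 of 37 fell and 2 rose over all genes, 7 fell and 3 rose over the list alone, and the median was −0.58 (adjusted p = 0.0282). Without estradiol with astrocytes replicate 2 that list had an adjusted p of 0.182, and with the array SD as covariate it turned upward (0.848). Cholesterol synthesis (median −0.70, adjusted p = 0.0233), glycolysis (−0.56, 0.0101) and the heat shock response (−0.72, 0.0358) had negative medians, each with an adjusted p = 0.597 with an estimated correlation and at percentiles 72.3, 91.5 and 39.9 of random lists matched on level. Without estradiol with astrocytes replicate 2 these 3 lists had adjusted p of 0.225, 0.214 and 0.463, and with the array SD as covariate each turned upward without passing (0.303, 0.380 and 0.0882).

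Epithelial markers (median 0.48, adjusted p = 0.0263), microglia and macrophage markers (0.61, 0.00608) and neuron markers (0.64, 0.00459) had positive medians under estradiol, each with an adjusted p = 0.579 with an estimated correlation. At percentiles 88.3, 87.4 and 83.8, all 3 lay inside the middle 95% of random lists matched on level. Over all genes ST14 (0.94), CD14 (1.04), SPI1 (1.28) and INA (0.93) rose, while CRB3 (1.18) and GAD2 (0.96) did not pass, and without estradiol with astrocytes replicate 2 ST14, CRB3 and GAD2 were at 0.61, 0.67 and 0.57. Adjusted over the list alone, 5 epithelial, 3 microglial and 9 neuronal genes rose and 1 neuronal gene fell. With the array SD as covariate the adjusted p of these lists was 0.0760, 0.787 and 0.491. Astrocyte markers did not pass under vehicle (28 measured, median 0.28, adjusted p = 0.0948) or under estradiol (median 0.50, adjusted p = 0.0653), where their median lay at percentile 99.6 of matched lists.

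**Figure D3:**
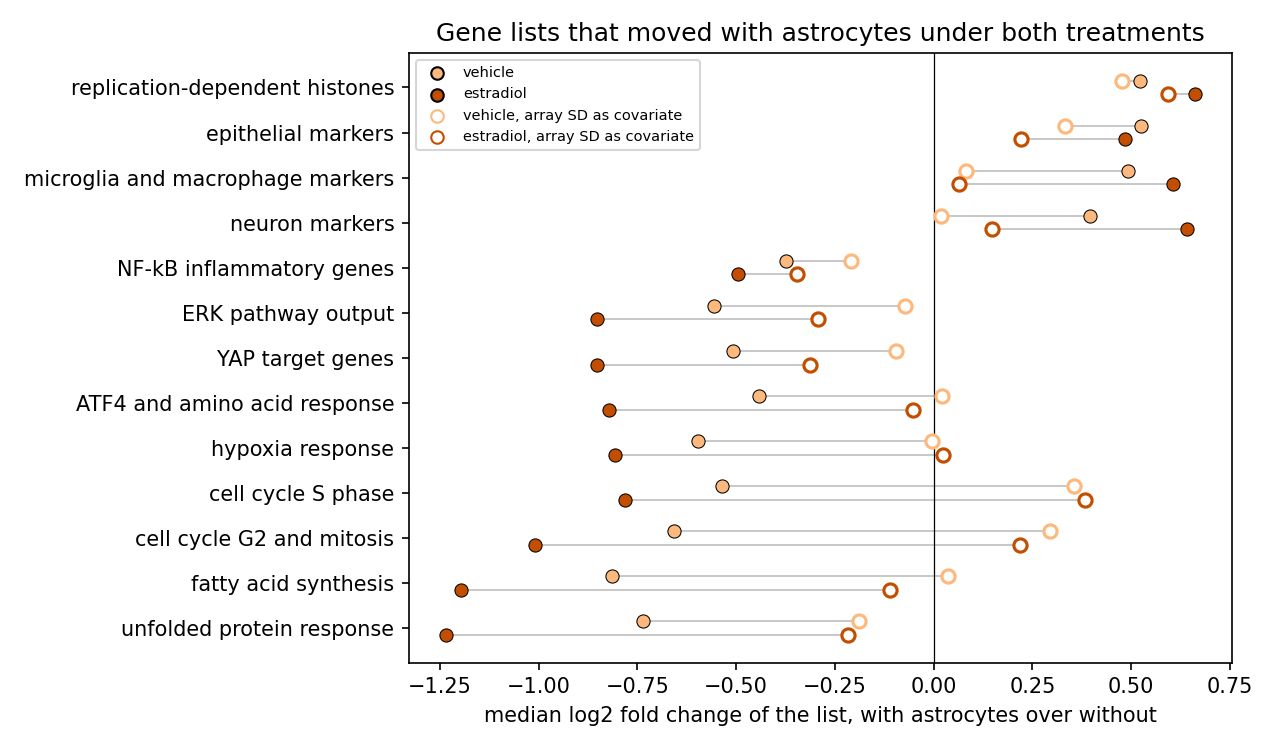
Median log2 fold change, with astrocytes over without, of each gene list that passed under both vehicle and estradiol; filled points are the values as reported and open points those with the array SD as covariate. The histone list stays at 0.48 and 0.59 with the covariate, while the S phase list and the G2 and mitosis list move from negative to positive medians.

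Of the 6 genes fixed before the data were examined for their role in estrogen signalling or invasion, EGFR (probe set 8132860), the receptor for epidermal growth factor, fell with astrocytes under estradiol by 1.81 (SE 0.44), from 9.12 ± 0.13 (SD, n = 3) to 7.31 ± 1.00 (SD, n = 3). S100A4 (probe set 7920271), a calcium-binding protein gene linked to metastasis, rose by 1.13 (SE 0.24), from 4.58 ± 0.19 (SD, n = 3) to 5.71 ± 0.52 (SD, n = 3). Their adjusted p in limma was 0.0368 and 0.0338 over all genes, and 0.00483 and 0.00372 over the list alone. ESR1, which encodes estrogen receptor alpha, was at 1.00, with an adjusted p of 0.0679 over all genes and 0.0328 over the list alone, in a group of dim genes whose median change was 0.58. PGR (0.64), ESR2 (0.19) and GPER1 (−0.07) did not pass, and under vehicle none of the 6 passed, with EGFR at −1.09 (adjusted p = 0.146), ESR1 at 0.60, PGR at 0.39, ESR2 at 0.21, S100A4 at 0.11 and GPER1 at 0.02. With the array SD as covariate EGFR was −0.77 (adjusted p = 0.122) and S100A4 0.66 (adjusted p = 0.0675) under estradiol, with quantile normalization S100A4 had an adjusted p of 0.0588, and under vehicle S100A4 turned to −0.25. Leaving out each of the 12 arrays in turn moved the adjusted p of EGFR under estradiol to between 0.00592 and 0.155 and that of S100A4 to between 0.00560 and 0.155. Both calls were lost without any 1 of the estradiol alone arrays, without vehicle alone replicate 1 or 2 and without estradiol with astrocytes replicate 3, and that of EGFR also without estradiol with astrocytes replicate 2. Without that array PGR under estradiol was at 0.30, ESR2 turned to −0.036 and EGFR passed under vehicle (adjusted p = 0.0203). Without estradiol with astrocytes replicate 1, ESR1 and PGR passed under estradiol (0.0124 and 0.0258) and ESR2 was at 0.39. Without vehicle with astrocytes replicate 2, ESR1 was at 0.27 and PGR at 0.21 under vehicle, and ESR2 ran from 0.069 to 0.37, GPER1 from −0.10 to 0.16 and S100A4 from 0.055 to 0.16 there without single arrays.

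The changes with astrocytes followed the level of signal. With genes split into 10 equal groups by their level in vehicle alone, the median change in the 4 dimmest groups lay between 0.36 and 0.43 under vehicle and between 0.50 and 0.58 under estradiol. In the 2 brightest groups it was −0.66 and −0.50 under vehicle and −0.96 and −0.89 under estradiol. The estradiol comparison among arrays with astrocytes ran from 0.11 in the dimmest group to −0.32 in the brightest, and the one without astrocytes stayed between −0.03 and 0.05.

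**Figure D4:**
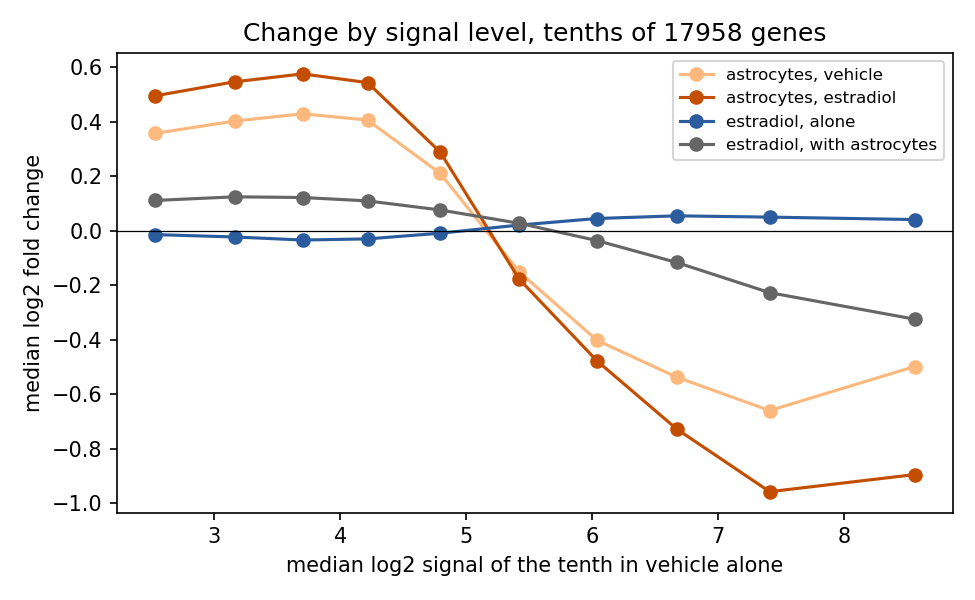
Median log2 fold change (vertical axis) in each of 10 equal groups of genes, against the group's median log2 signal in vehicle alone (horizontal axis), for the 4 pairwise comparisons. With astrocytes the 4 dimmest groups lie above 0 and the brightest below 0, down to −0.66 under vehicle and −0.96 under estradiol.

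Estradiol against vehicle in cells cultured alone asks whether the hormone acts on the tumour cells directly. ESR1 (−0.16), ESR2 (0.17), GPER1 (−0.04), PGR (−0.02), EGFR (0.06) and S100A4 (−0.19) did not pass, with an adjusted p of 0.952 for each over the list alone. Without single arrays ESR1 ran from −0.31 to −0.019, ESR2 from 0.028 to 0.33 and S100A4 from −0.30 to −0.11. The genes with the smallest unadjusted p included PMS2CL (0.53, SE 0.24), AQP7 (0.41, SE 0.20), CFAP73 (0.55, SE 0.27) and TYW1 (−0.41, SE 0.22), all with an adjusted p of 1.00. PMS2CL ran from 0.32 to 0.70 without single arrays. The 29 measured estrogen receptor target genes had a median of 0.06 and did not pass (adjusted p = 0.269). No gene of 17958 passed in limma, 1 had an unadjusted p under 0.05, where 898 are expected by chance, and with array weights 8 passed. So few small p-values point to a spread too wide for these arrays, so the lack of calls does not show a lack of effect. The fit gave a median SE of 0.30 in every pairwise comparison. Within groups, arrays with astrocytes correlated down to r = 0.759, against 0.961 or more without. Small p-values were also fewer than expected for estradiol with astrocytes and for the interaction. Signals did not overlap for 3.21% of genes, against 10% by chance. That share does not use the fitted spread, so a wide SE alone does not account for it. Between the 2 groups without astrocytes the deviations of arrays from their group means correlated at r from −0.751 to 0.760. Whether this lowered the share was not tested.

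Small rises passed camera in 4 lists under estradiol alone. These were NF-kB inflammatory genes (33 genes, median 0.07), antigen presentation (20 genes, median 0.09), oxidative phosphorylation (42 genes, median 0.08) and cytosolic ribosomal proteins (40 genes, median 0.06), each with an adjusted p of 0.0216. No member passed over all genes or adjusted over the list alone. None held with an estimated correlation (adjusted p = 0.195 for NF-kB inflammatory genes and adjusted p = 0.998 for the other 3). The number of lists was 0 without estradiol alone replicate 1 or vehicle alone replicate 3, 1 without estradiol alone replicate 3, 2 without vehicle alone replicate 2 and 7 without vehicle alone replicate 1. With the array SD as covariate only NF-kB inflammatory genes passed (adjusted p = 0.0425), but not with the correlation estimated in that fit (0.283).

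Estradiol against vehicle in cells cultured with astrocytes addresses the title's question. UGT2B7 (probe set 8100758), which encodes an enzyme that glucuronidates steroids, lay at 3.95 ± 0.17 (SD, n = 3) with estradiol against 2.38 ± 0.27 (SD, n = 3) with vehicle. S100A4 lay at 5.71 ± 0.52 (SD, n = 3) against 4.88 ± 0.11 (SD, n = 3), and no array of either group overlapped the other. Neither passed over all genes. In limma UGT2B7 differed by 1.58 (SE 0.22) with an adjusted p of 0.215, and it passed with the array SD as covariate (0.0150) and with array weights (0.000324). Those weights were 0.244, 0.0224 and 151 for replicates 1, 2 and 3 of estradiol with astrocytes. The weighted fit therefore rests almost wholly on 1 array of that group, and the signal of UGT2B7 is near background. S100A4 differed by 0.83 (SE 0.24), with an adjusted p of 1.00 over all genes and 0.0337 over the list alone, and by 0.54 without estradiol with astrocytes replicate 2. With the arrays of these groups taken as 3 pairs by replicate number, a choice made after seeing the data, UGT2B7, S100A4 and ESR1 were higher with estradiol in every pair, with adjusted p of 0.0868, 0.764 and 0.767, and no gene passed in limma. EGFR was at −0.66, ESR1 at 0.24, PGR at 0.23, ESR2 at 0.15 and GPER1 at −0.13, none past the threshold over all genes or over the list alone. Single arrays carry these values: EGFR was at −1.08 without estradiol with astrocytes replicate 1, −0.10 without its replicate 2 and −0.29 without vehicle with astrocytes replicate 1, and ESR1, PGR and ESR2 turned to −0.077, −0.11 and −0.076 without estradiol with astrocytes replicate 2. GPER1 ran from −0.28 to −0.016 without single arrays. MGC70870 (−0.76), CDK11B (−0.76), PTCHD3 (0.74) and CPN1 (0.73) had small unadjusted p-values and did not pass. No gene of 17958 passed in limma, 142 had an unadjusted p under 0.05, where 898 are expected by chance, and with array weights 1197 passed. Signals did not overlap for 2.18% of genes, against 10% by chance.

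With astrocytes present, estradiol went with a higher type I interferon response list. Of 41 measured genes, 30 had positive changes, the median was 0.16 and the adjusted p was 0.0149. No member passed over all genes or adjusted over the list alone, and with an estimated correlation the list did not pass (adjusted p = 0.896). The call held without estradiol with astrocytes replicate 2 (adjusted p = 0.00511) and with the array SD as covariate (0.00191, and 0.643 with the correlation estimated in that fit), but not without estradiol with astrocytes replicate 1 or vehicle with astrocytes replicate 2, up to 0.532. Histones were higher (median 0.21, adjusted p = 0.000316), and ERK pathway output (median −0.26, 0.000361) and YAP target genes (median −0.25, 0.000311) were lower. All 3 lists had an adjusted p = 0.896 with an estimated correlation, and without estradiol with astrocytes replicate 2 their adjusted p was 0.299, 0.951 and 0.916. Without vehicle with astrocytes replicate 1 none of the 3 passed either. No list was set against random lists matched on level in this comparison or in the interaction. Across 10 groups of genes by level, the median change with estradiol here ran from 0.11 in the dimmest to −0.32 in the brightest.

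Lower values in 5 more lists turned into higher ones without estradiol with astrocytes replicate 2. The G2 and mitosis list went from lower (median −0.27, adjusted p = 0.00200) to higher (1.18e-05), and the S phase list from lower (−0.23, 0.0267) to higher (3.21e-06). Fatty acid synthesis went from 0.0149 to 0.0163, glycolysis from 0.0436 to 0.0181 and the heat shock response from 0.0188 to 0.00911, each from lower to higher. None of the 5 lists passed with an estimated correlation (adjusted p = 0.896). Without vehicle with astrocytes replicate 1 none of the 5 passed, and without replicate 3 of that group only fatty acid synthesis did. The total number of lists was 16 without estradiol with astrocytes replicate 1 or 3 or vehicle with astrocytes replicate 2, 15 without estradiol with astrocytes replicate 2, and 1 without vehicle with astrocytes replicate 1. With the arrays taken as 3 pairs it was 14, the 9 above among them. The estrogen receptor target genes did not pass here either (median −0.02, adjusted p = 0.911).

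The interaction asks whether estradiol acted differently with astrocytes than without. The difference was 1.40 (SE 0.31) for UGT2B7, 1.02 (SE 0.35) for S100A4, 0.83 for NHLRC1, 0.83 for ZRSR2, −0.84 for AQP7 and −0.92 for RAD52. None passed over all genes, and S100A4 had an adjusted p of 0.0738 over the list alone. No gene of 17958 passed in limma, 31 had an unadjusted p under 0.05, and with array weights 648 passed. The weighted fit rests almost wholly on replicate 3 of estradiol with astrocytes for that group. The changes with estradiol in the presence and in the absence of astrocytes correlated at r = −0.142 across genes. For the NF-kB, histone and other astrocyte changes described above, the limma fit as reported therefore showed no gene whose effect differed between vehicle and estradiol.

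By camera 10 lists passed for the interaction, histones as more positive with astrocytes (median 0.16, adjusted p = 0.00305) and 9 as more negative, among them ERK pathway output (median −0.31, 8.96e-05) and YAP target genes (median −0.32, 0.00106). None passed with an estimated correlation (adjusted p = 0.810). Without estradiol with astrocytes replicate 2 these 3 lists had adjusted p of 0.299, 0.401 and 0.864, and the G2 and mitosis list turned from more negative (0.00202) to more positive (0.000138). That fit gave 13 lists, 10 more positive and 3 more negative, and none of them shared both call and direction with the 10. The number of lists was 5 without estradiol alone replicate 1, 4 without vehicle alone replicate 3, 18 and 16 without estradiol with astrocytes replicates 1 and 3, and 0 and 6 without vehicle with astrocytes replicates 1 and 3.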

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

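The tests on probe sets without a gene, on the olfactory receptor genes, on astrocyte markers and on NF-kB inflammatory genes with the array SD as covariate were chosen only after the result was seen.

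Signal changed in probe sets outside the comparisons of genes. Of the 12061 probe sets with no gene in the probe table, 3479 were higher and 1766 lower with astrocytes in the mean of both astrocyte comparisons, 43.5% in all, against 45.8% of the probe sets with 1 gene. Estradiol without astrocytes changed 0 of them in limma. Their median level in vehicle alone was 3.42, against 5.08 for probe sets with 1 gene. With the array SD as covariate 665 were higher and 730 lower.

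Dim genes rose and bright genes fell with astrocytes. The 335 olfactory receptor genes, which are expected to be silent in these cells, had a median change of 0.54 in the mean of both astrocyte comparisons, 0.25 with quantile normalization, which gives every array the same range, and 0.38 with arrays centred, so a narrower signal range as the cause stays open; the 0.023 with the array SD as covariate decides nothing, because dim genes that rise lower the SD themselves. RNA of mouse astrocytes carried through the sort stays open too: the 28 astrocyte markers had a median of 0.46, at percentile 99.78 of random lists matched on level, whose middle 95% ran from −0.19 to 0.37. Against a single source, GFAP (0.95), BCAN (1.07), MT3 (0.99) and CST3 (0.67) were higher while SLC1A3 (−0.94), CPE (−0.83) and GJA1 (−0.64) were lower, human probes need not bind mouse RNA, 12 of the 28 lie above the median level of genes in vehicle alone, 4 are in another list, the EGFP sort was meant to remove astrocytes, and 6 of the 40 lists lay above the range of their own matched lists. A response of the tumour cells to astrocytes was not separated from either by these tests, since SD and culture go together in this design.

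Long genes fell more than short genes with astrocytes. Among the 5384 bright genes the median change went from −0.11 in the shortest of 5 equal groups by length to −1.01 in the longest under vehicle, and from −0.30 to −1.32 under estradiol. At equal array SD the slope of signal on log gene length still differed by −0.0934 between arrays with and without astrocytes (95% interval −0.160 to −0.0266). Without the adjustment it differed by −0.147. Signal range as the whole cause is not settled by this, because SD and culture go together in this design. Whether range plays a part cannot be told apart from chance with 12 arrays: within groups the slope and the SD correlated at r = 0.641 (permutation p = 0.126; rho = 0.713, permutation p = 0.0628), and at r = 0.452 without replicates 1 and 2 of estradiol with astrocytes. RNA damaged during sorting and a change in transcription remain open and untested.

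NF-kB inflammatory genes fell with astrocytes under both treatments. With the array SD as covariate the list stayed lower in the mean of both comparisons, with a median of −0.30 and an adjusted p of 2.37e-05 in camera. That p was 0.0367 with the correlation estimated as well, although without the covariate the list did not pass with an estimated correlation (0.390). Whether a narrower signal range is the whole cause stays open, because SD and culture go together in this design. The covariate also moved the brightest of 10 groups of genes by level to a median of 0.27. Matched on level and gene length, its median of −0.37 lay at percentile 0.16 of random lists, whose middle 95% ran from −0.23 to 0.29. That argues against level and length as the cause, but only weakly. Of the 40 lists 5 lay above and 3 below such a range, and the unfolded protein response list lay lower still, at 0.01. On level alone the NF-kB list lay inside the range of matched lists, at percentile 11.24, and at 4.34 under vehicle and 7.19 under estradiol. A lower inflammatory programme in tumour cells next to astrocytes may therefore be worth following up, as a hypothesis found and tested on the same data. Cell handling during co-culture, which the design joins to the culture, is untested. Sorting is untested too, and any difference in it between cells alone and cells from co-culture would go with the culture.

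Other splits of the same arrays were counted. For the mean of both astrocyte comparisons 1 of 100 splits, the real one, gave as many genes, 8528 against a highest other of 7722. The real split thus gave the most genes of those drawn, for a comparison that was itself chosen after seeing the data. The labels do not say whether replicates were separate cultures, so this count cannot exclude chance between cultures or an effect of handling. Without vehicle alone replicate 1 or 2, estradiol alone replicate 1 or vehicle with astrocytes replicate 2 the real count was 4770, 5118, 4980 and 5234. No other split was counted with an array left out, so these counts cannot be set directly against 7722. The split with 7722 exchanged vehicle alone replicate 3 and vehicle with astrocytes replicate 1, and it was the only 1 of the others with over 1000 genes. With 10 splits of 6 arrays, which are too few for a share under 0.05, the real split gave 10 genes with astrocytes under vehicle (1 split with as many, highest other 0) and 2366 under estradiol (1 split, highest other 0). Where the real count is 0 every split gives as many, so the splits decide nothing on chance. This holds for estradiol alone, with 0 genes in limma (1 unadjusted), 10 of 10 splits and a highest other of 0, and for the interaction, with 0 genes (31 unadjusted), 100 of 100 splits and a highest other of 1. It also holds for estradiol with astrocytes, with 0 genes (142 unadjusted) and 10 of 10 splits, and for the 4 of these, the real one among them, that part all 3 pairs of arrays with the same number, which gave 0 genes each. The highest other there was 2709, in the split that put estradiol replicates 1 and 3 with vehicle replicate 1, which parts only 1 of the 3 pairs and points to a structure of the samples other than treatment.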

How the results depend on the processing

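The array SD as covariate, leaving out replicate 2 of both astrocyte groups, pairing the astrocyte arrays by number and the mean of both astrocyte comparisons were chosen after seeing the data. Counts follow the order estradiol alone, estradiol with astrocytes, astrocytes under vehicle, astrocytes under estradiol, interaction and mean of both astrocyte comparisons, and those not given stayed within 1.5 times; the cause was not tested except where stated. As reported they were 0, 0, 10, 2366, 0 and 8528 in limma. Array weights gave 8, 1197, 12445, 14777, 648 and 14987, with weights from 0.0224 to 151 on single arrays. Both extremes fell in estradiol with astrocytes, on replicates 2 and 3, so for that group the fit rests almost wholly on 1 array. The replicate block gave 2583 under vehicle and 6691 under estradiol, although over the 4 groups the numbers pair the arrays only in part. Of pairs with the same number 10 of 18 had r over 0.1, from −0.493 to 0.789, against 10 of 36 with other numbers. Of 12 arrays 7 correlated best with their own number. Between the 2 astrocyte groups all 3 pairs had r over 0.1, although replicate 3 of estradiol with astrocytes correlated more with replicate 1 of vehicle with astrocytes (r = 0.396). With the arrays of these groups paired by number, estradiol gave 0 genes and 14 lists, and the pairing changed no call of a named gene. The array SD as covariate gave 1 for estradiol with astrocytes, then 1166, 469 and, for the mean, 2584. Without both replicates 2, astrocytes under vehicle gave 1004. Centring gave 4 under vehicle, and moved the median of all genes from 0.06 to −0.09 under vehicle and from 0.07 to −0.11 under estradiol. Genes above the median level gave 5 under vehicle and 4118 for the mean (fewer genes tested). Every probe set gave 700, 5049 and 15009 for the astrocyte comparisons (more features tested). No moderation gave 28 and 125. The 6 arrays of the compared groups gave 1594 under vehicle and 0 under estradiol (fewer arrays). Quantile normalization gave 529 under estradiol. An unadjusted p under 0.05 with at least 1.5-fold gave 68, 4510, 7202 and 31 for estradiol with astrocytes, astrocytes under vehicle and under estradiol, and the interaction. Without single arrays the counts ran from 2 to 6107 under vehicle, 3 to 9222 under estradiol and 4770 to 11339 for the mean, and stayed at 0 for the other 3. Lists past the threshold were 4, 9, 14, 18 and 10. With an estimated correlation they were 0, 0, 0, 0 and 0; with a correlation of 0.05 they were 0, 3, 2, 9 and 2; with fry 0, 0, 2, 4 and 0. Genes above the median level gave 3 lists for each of estradiol with astrocytes, both astrocyte comparisons and the interaction. The array SD as covariate gave 1, 5, 7, 11 and 5 (0, 0, 0, 1 and 0 with an estimated correlation), and leaving out both replicates 2 gave 5 for estradiol with astrocytes and 2 for the interaction. Without single arrays the lists ran from 0 to 7, 1 to 16, 11 to 16, 15 to 20 and 0 to 18. Of 150 values of named genes, 123 kept their direction and side of the threshold with the replicate block, 114 with quantile normalization, 95 with array weights, 90 with the array SD as covariate and 123 without both replicates 2. Without single arrays of the groups compared 691 of 990 values did, 254 lost their call, 25 gained one and 20 turned. PTGS2 and IL6 kept their calls in both astrocyte comparisons under these 5 alternatives and without any single array, but under estradiol they lost them in the fit of the 6 arrays of the compared groups. Direction turned with the array SD as covariate for EGFR (−0.017) and PGR (0.031) under estradiol alone, for ESR1 (−0.039), ESR2 (−0.028), PGR (−0.15) and S100A4 (−0.25) with astrocytes under vehicle, and for ESR2 (−0.13), GPER1 (0.17) and PGR (−0.068) with astrocytes under estradiol. It turned with quantile normalization for PGR under estradiol alone (0.00073), ESR2 with astrocytes under vehicle (−0.075) and ESR2 (−0.10) and GPER1 (0.25) with astrocytes under estradiol. It turned with array weights for PGR under estradiol alone (0.035), H2BC4 under estradiol with astrocytes (−0.032) and ESR2 in the interaction (0.013), and without both replicates 2 for ESR2 with astrocytes under estradiol (−0.036). Without single arrays it turned under estradiol alone for EGFR (−0.079 to 0.15), GPER1 (−0.12 to 0.0099) and PGR (−0.13 to 0.12), and under estradiol with astrocytes for ESR1 (−0.077 to 0.57), ESR2 (−0.076 to 0.35) and PGR (−0.11 to 0.50). It also turned for GPER1 with astrocytes under vehicle (−0.10 to 0.16) and under estradiol (−0.15 to 0.0076), ESR2 with astrocytes under estradiol (−0.036 to 0.39), and ESR2 (−0.24 to 0.19), GPER1 (−0.24 to 0.028) and PGR (−0.088 to 0.52) in the interaction. Signal near background limits PGR and UGT2B7, whose mean lay at percentiles 8.15 and 8.45 of all genes, and ESR1, at percentile 25.6, is dim too.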

Other observations

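The mean of both astrocyte comparisons, the families of genes grouped by name, with their camera tests and their values under each scaling, and the tests with the array SD as covariate were chosen only after the result was seen.

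Zinc finger genes, most of which encode transcription factors, are 1 of 8 families tested with camera and adjusted over the 8. The median change of 433 ZNF genes was −0.34 under vehicle (adjusted p = 3.66e-06) and −0.33 under estradiol (adjusted p = 0.000586), but neither passed with an estimated correlation (adjusted p = 0.756 and adjusted p = 0.767). Under estradiol 61 fell and 17 rose over all genes in limma, 14.1% and 3.93%, against 8.15% and 5.03% of all 17958 genes. For both comparisons together the median was −0.42 with quantile normalization, −0.50 with arrays centred and −0.16 with the array SD as covariate. The 63 keratin-associated protein genes, normally expressed in hair, had medians of 0.44 and 0.63, and 6 rose and none fell under estradiol; for both together the median was 0.40 with quantile normalization, 0.33 with arrays centred and −0.02 with the covariate. Genes of 2 essential complexes had no direction that held under every scaling. The 71 mitochondrial ribosomal protein genes had a median of −0.12 under vehicle and −0.29 under estradiol, but 0.28 and 0.14 with quantile normalization and 0.57 and 0.56 with the covariate. The 36 proteasome subunit genes had medians of −0.30 and −0.67, but 0.08 and −0.26 with quantile normalization and 0.48 and 0.36 with the covariate.

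In the mean of both comparisons 8528 of 17958 genes passed, 4392 higher and 4136 lower on the arrays with astrocytes. The design does not separate a response of the tumour cells from signal range or handling, which go with the culture. PTGS2 fell by 2.60 (SE 0.16), IL6 by 2.17 (SE 0.15), IL1B by 2.83 (SE 0.34) and CSF3 by 1.26 (SE 0.13). EGFR fell by 1.45 (SE 0.31) and ESR1 rose by 0.80 (SE 0.25), with adjusted p in limma of 0.00714 and 0.0256, though ESR1 was at −0.039 under vehicle with the array SD as covariate. ESR1 (3.61 in vehicle alone) lies in a group of dim genes with a median of 0.50 (SD 0.42 across its genes), and EGFR in the brightest, with a median of −0.69 (SD 0.64 across its genes). The ESR1 call was lost without estradiol alone replicate 1 or 3, vehicle alone replicate 1 or 2, or vehicle with astrocytes replicate 2, up to an adjusted p of 0.0666. The count was 2584 with the array SD as covariate, of which 1421 were among the 8528, and leaving out single arrays gave 4770 to 11339 genes. Those that moved it by over 1.5 times were vehicle alone replicates 1 (4770) and 2 (5118), estradiol alone replicate 1 (4980) and vehicle with astrocytes replicate 2 (5234).

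Oxidative phosphorylation and cytosolic ribosomal protein genes did not pass with astrocytes, but with the array SD as covariate both lists were higher, with adjusted p of 1.09e-09 and 0.000149 under vehicle and 1.05e-10 and 7.21e-05 under estradiol. With the correlation estimated in that fit neither passed (adjusted p = 0.747 for both under vehicle and adjusted p = 0.548 for both under estradiol). The covariate raised the brightest of 10 groups of genes by level too, to a median of 0.27 in the mean of both comparisons. Without it the 2 lists lay at percentiles 99.94 and 100 of random lists matched on level under vehicle and 99.96 and 100 under estradiol. Matched on length as well, they lay at 90.76 and 98.8 in the mean of both comparisons.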
